A study of Mus musculus with 165 samples.

How the data were processed

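RNA of C2C12 myotubes was sequenced in 39, 54, 42 and 30 libraries of 4 batches. The authors deposited RSEM 1.3.3 expected counts, a file per library, on the mouse build mm10, with 48795 gene identifiers each. Symbols were matched from the GENCODE M21 annotation for 48349 of them, and 126 identifiers shared a symbol. Values were estimates rather than whole counts, 7.61 to 9.9% of them not whole numbers per library, and were rounded for the count models. Libraries held 13.65 to 44.38 M counts. The 20 largest genes took 8.81 to 13.79% of counts per library. No library was left out of the results as reported, and 0 pairs of libraries held identical values.

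Groups, batches and controls were read from the sample labels. In the labels of the ethanol samples the treatment field reads JGW where the title reads JGE, and the title was followed, and a ratio written 2:! in 6 labels at 20 µg/mL was read as 2:1. The labels give each library a batch, A to D, which entered each fit that spanned batches as a covariate. Water and ethanol extracts were compared with untreated libraries, since the labels name no solvent control for extracts. The 6 compounds were compared with the vehicle libraries of batch D. Untreated and vehicle libraries lay in library sets of their own, apart from those of extracts and compounds. Vehicle and untreated libraries were compared in batches A, B and D, since batch C has no vehicle library in this set.

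Differential expression used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test (glmQLFit with legacy off, glmQLFTest), 2-sided. Genes tested numbered 14347 to 16055. P-values were adjusted by Benjamini-Hochberg within a comparison and called at 0.05. Extract fits held all libraries of 1 dose and the untreated libraries, with 1 coefficient per preparation, and contrasts took means over preparations. Slopes used the 63 libraries of a solvent, with 1 coefficient per preparation and 1 slope on the dose in 5-fold steps. The 27 comparisons were fixed before the data were examined, and 3 contrasts between solvents were added afterwards. Fits with a standard error above 20 on the log2 scale were not used as tests of a single gene, 0 to 74 genes per comparison.

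The 31 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A list needed 3 tested members. Of 930 list tests 381 passed, and 196 passed with the correlation estimated per list, all of which also passed with the preset. Counts of members past the test are given over all genes tested and adjusted over the list alone.

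Named genes followed a rule fixed before the data were examined. The 10 largest rises and 10 largest falls past the test were eligible, with an average log2 CPM of at least 1, no predicted-gene or clone name, and the same sign in each preparation or library. Up to 4 members of each described list, those with the smallest adjusted p and the same minimum level, and a few label-check genes for the compounds were added. Genes of these sets that the text does not name were left out for length. Folds against groups with 0 counts used a floor of 3 counts over the group, and with 1 to 4 counts the ratio is given with its 95% exact binomial interval. Intervals and floors cover counting error alone.

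Levels are in CPM scaled by TMM over all libraries. Untreated levels average same-numbered libraries first, so n = 3. Relations across libraries used Pearson and Spearman coefficients with permutation tests. The distance between 2 libraries was the median over genes of the squared deviation of their counts from the split expected by depth. It was divided by the value expected from sampling noise, so it is a ratio of variances. Alternatives tried were DESeq2 size factors, the DESeq2 test, no low-count filter, no batch term, all libraries in 1 fit, each batch alone, the other control, the replicate number as a block and leaving out the libraries of each number. Fragment length or mitochondrial share as a covariate, low-mitochondrial libraries left out and same-numbered controls summed were added after the data were seen. Other tools were the R package data.table (1.17.8), numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 under Python 3.11.15, and DESeq2 1.42.0 for the alternative size factors and Wald test.

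A self-test changed known genes in simulated counts before the comparisons were read. The counts of a gene were drawn from its mean level and fitted spread. They held no batch shifts, near-repeat controls or shared component, so the rates hold for independent libraries only. With the libraries of 1 preparation at 500 µg/mL, 40.3, 83.6 and 96.9% of genes changed 1.5, 2 and 4-fold were recovered, with 9 false calls (5.8%). With 7 preparations, 77.3, 95.5 and 100% were recovered, with 11 false calls. For the vehicle comparison it was 92.4, 100 and 100%, with 14 false calls (6.9%), and for 1 compound 30.3, 70.8 and 96.9%, with 6 false calls (4.4%). For the slope 100% was recovered at each size, with 9 false calls (4.4%). The changed list was called in each of these tests, and 0 of 30 random lists.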

Results

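The series asked how the mixing ratio, the order of mixing and extraction, and the solvent of Jakyakgamcho-tang, a decoction of peony and licorice, change gene expression in cultured cells. The libraries read here came from C2C12, a mouse myoblast line, after differentiation into myotubes, and the deposited values were RSEM expected counts on the mm10 build. Each of 14 preparations, 7 made with hot water and 7 with 70% ethanol, was given at 20, 100 and 500 µg/mL with 3 libraries per dose. The labels do not say which herb is written first in a ratio, so the preparation at 3:0 is called the first herb and that at 0:3 the second herb. Untreated and vehicle (0.02% DMSO) cultures and 6 pure compounds completed the set, which fell into 4 batches called A to D (39, 54, 42 and 30 libraries). Libraries held 13.65 to 44.38 M counts (median 29.77 M), and 17965 to 20685 genes were detected per library (median 19728). Median depth was 30.65, 27.71, 30.01 and 33.47 M in batches A, B, C and D. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, not between cultures. Untreated libraries of the same number were near-repeats across batches (1.12 to 1.52 times the variance of sampling noise), as were vehicle libraries. The reported fits counted each of them as a separate library. Standard errors and p-values against controls of more than 1 batch may therefore be too small. Gene values are log2 fold changes ± SE from edgeR, 2-sided, and a gene is said to rise or fall where its Benjamini-Hochberg adjusted p was under 0.05. Gene lists were fixed before the data were examined and tested with limma camera, whose adjusted p stands beside each count.

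Transcripts of the mitochondrial genome took 0.14 to 6.04% of counts (median 4.12%). The share averaged 4.34% in 12 untreated libraries (3.55 to 5.03) and 4.48% in 9 vehicle libraries (3.98 to 4.92). Water extracts held 4.33, 4.54 and 4.63% at 20, 100 and 500 µg/mL (n = 21 each). Ethanol extracts held 2.77% ± 1.63, 2.68% ± 1.78 and 2.22% ± 1.33 at the same doses (SD, n = 21 each), and compounds 1.90% ± 1.09 (SD, n = 18). Among ethanol extracts the mean was 4.07% in batch B, 1.97% in batch C and 1.80% in batch D. Of 20 libraries under 1%, called low-mitochondrial libraries from here on, 4, 5 and 5 were ethanol extracts at 20, 100 and 500 µg/mL and 6 were compounds. Component 1 of 11729 genes held 39.9% of the variance over all libraries. It followed the mitochondrial share at Pearson r = −0.94 and Spearman rho = −0.89 (permutation p = 1e-05 for each, the smallest possible), and at r = −0.91 and rho = −0.90 within groups. It followed the mean fragment length at r = −0.83 and rho = −0.79 (permutation p = 1e-05 for each), and at r = −0.74 and rho = −0.73 within groups. Without the 2 libraries farthest from the median, r was −0.94 for the mitochondrial share and −0.81 for fragment length.

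**Figure D1:**
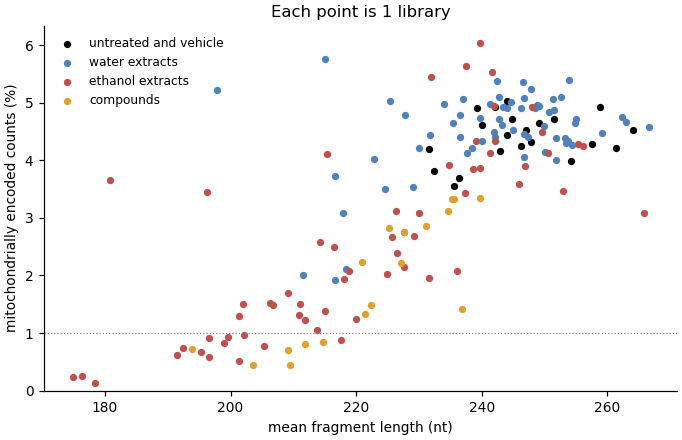
Mitochondrially encoded counts (%, linear axis) against mean fragment length (nt) for each library of the 4 batches, coloured by treatment, with a dotted line at 1%. Untreated libraries averaged 4.34% and 240.7 nt, and the 20 libraries under the line were ethanol extracts or compounds.

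Untreated libraries with the same number in different batches differed from each other by 1.12 to 1.52 times the variance of sampling noise (median 1.32, 18 pairs). Untreated libraries with different numbers differed by 1.63 to 4.12 times (median 2.74, 36 pairs). For vehicle libraries the medians were 1.34 (9 pairs) and 2.08 (18 pairs), and for 3 libraries of an extract group 6.14 (126 pairs). The 12 untreated libraries thus formed 3 sets by number, closer within a number across batches than between numbers within a batch (median 2.63, 12 pairs).

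Water extracts at 500 µg/mL raised genes of xenobiotic metabolism and lowered genes of cell division against untreated cultures (21 against 12 libraries, mean of 7 preparations). All 7 tested targets of the aryl hydrocarbon receptor rose (7 adjusted over the list alone, median 2.91, camera adjusted p = 6.0e-22). Cyp1b1, which oxidises polycyclic aromatic compounds, rose by 2.79 ± 0.06 in the mean of the 7, and with the second herb alone by 3.09 ± 0.07, from 53.2 ± 1.87 CPM in untreated cultures (SD, n = 3) to 451 ± 13 CPM (SD, n = 3). Aldh3a1, an aldehyde dehydrogenase, rose by 4.13 ± 0.12 and Ahrr, the receptor's repressor, by 3.28 ± 0.22. Cyp1a1 held 0 counts in all 12 untreated libraries and 1448 over 21 treated ones, at least 252-fold against a floor of 3 counts, which still places it above the list median. Of 27 Nrf2 targets, which serve the response to oxidants, 20 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 1.7e-22). The glutathione transferase genes Gsta1, Gsta4 and Gstm1 rose by 4.17 ± 0.13, 3.09 ± 0.12 and 1.74 ± 0.08. Gsta1 has a close paralogue, Gsta2, so the counts of either may include reads of the other.

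Cell division genes fell as a group under water extracts at 500 µg/mL, all 30 of 30 tested (30 adjusted over the list alone, median −1.51, camera adjusted p = 1.5e-58). Mki67, a marker of cycling cells, fell by 1.84 ± 0.09 and cyclin A2 (Ccna2) by 1.68 ± 0.05. Extracellular matrix genes fell in 16 and rose in 2 of 26 (18 and 2 adjusted over the list alone, camera adjusted p = 3.3e-09). Tagln (−1.82 ± 0.05) and Ccn2 (−1.25 ± 0.06), both responsive to TGF-beta, fell too. Hmgcs1, an enzyme of cholesterol synthesis, fell by 0.54 ± 0.05, with 12 of 23 cholesterol genes lower and 1 higher (12 and 2 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.05 with an estimated correlation). The chemokines Cxcl5 and Cxcl1, which attract neutrophils, rose by 4.90 ± 0.29 and 3.39 ± 0.20. Of 18 muscle atrophy genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0066), including the ubiquitin ligases Fbxo32 (0.50 ± 0.05) and Trim63 (0.33 ± 0.06). Contractile genes fell in 17 and rose in 3 of 45 (18 and 3 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.44 with an estimated correlation), and fell in 21 and rose in 7 without the low-mitochondrial libraries. No water or untreated library was among those, so that setting removed only ethanol libraries from the shared fit. With same-numbered controls summed into 1 library, 10 matrix and 10 contractile genes fell and 6 atrophy genes rose. Of 13 mitochondrially encoded genes and 32 nuclear respiratory chain genes 0 passed the edgeR test, adjusted over all genes. In all, 2278 genes rose and 2331 fell of 15910 tested. The total of 4609 was 2822 with same-numbered controls summed, 2481 without the libraries numbered 1, 5097 in batch A alone and 3624 in batch B alone.

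Ethanol extracts at 500 µg/mL raised targets of the aryl hydrocarbon receptor and Nrf2 (21 against 12 libraries, mean of 7 preparations), while genes of the hypoxia and integrated stress responses rose in the mean but not in each preparation. All 7 aryl hydrocarbon receptor targets rose (7 adjusted over the list alone, median 3.41, camera adjusted p = 1.6e-09), with Cyp1b1 up by 2.43 ± 0.05 and Cyp1a1 at least 2700-fold above a floor of 3 counts. Nrf2 targets rose in 25 of 27 (25 adjusted over the list alone, median 1.00, camera adjusted p = 8.8e-16), with Gsta4 up by 4.51 ± 0.11 and sulfiredoxin (Srxn1) by 1.50 ± 0.04. Of 27 hypoxia and glycolysis genes 22 rose and 2 fell (22 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 7.2e-11). The glucose transporter gene Slc2a1 rose by 1.87 ± 0.04, Ndrg1 by 1.99 ± 0.04 and the mitophagy receptor gene Bnip3 by 2.17 ± 0.06. The list median was −0.32 in JGE05 and 0.27 to 1.03 in the other 6 preparations. Targets of ATF4, the transcription factor of the integrated stress response, rose in 17 and fell in 7 of 26 (18 and 7 adjusted over the list alone, median 0.38, camera adjusted p = 0.0022). Gdf15, a secreted stress factor, rose by 2.59 ± 0.08 and Ddit3, which encodes CHOP, by 0.96 ± 0.06. The ATF4 median was 1.76 in JGE05, 0.89 in JGE04, 0.20 in JGE06, 0.19 in JGE07, −0.16 in JGE01 and −0.12 in JGE02 and JGE08. With same-numbered controls summed, 4 ATF4 targets fell.

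All 30 cell division genes fell under ethanol extracts at 500 µg/mL (30 adjusted over the list alone, median −1.80, camera adjusted p = 5.3e-24), with Ccna2 down by 2.53 ± 0.04 and Top2a by 2.68 ± 0.05. Myogenic regulators fell in 13 of 14 and rose in 1 (13 and 1 adjusted over the list alone, median −0.60, camera adjusted p = 1.2e-04), among them Myod1 (−0.70 ± 0.04) and Mef2c (−0.98 ± 0.07), transcription factors of muscle differentiation. Genes of the neuromuscular junction fell in 12 and rose in 2 of 16 (12 and 2 adjusted over the list alone, camera adjusted p = 9.9e-04), with acetylcholinesterase (Ache) at −1.39 ± 0.06. Contractile genes fell in 28 and rose in 7 of 45 (28 and 7 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.16 with an estimated correlation), and 4 rose with same-numbered controls summed. Their median was −0.97 in JGE05, −0.67 in JGE04 and 0.09 in JGE07, and that of myogenic regulators was −1.29 in JGE05 and −0.22 to −0.63 in the others. The muscle growth factor gene Igf1 fell by 3.49 ± 0.06 and Lgr5 by 4.52 ± 0.13. Fibroblast markers, read as a check for other cell types, fell in 8 and rose in 1 of 9 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0024), with Pdgfrb at −1.10 ± 0.04. Mitochondrially encoded genes fell in 12 of 13 (12 adjusted over the list alone, median −1.65, camera adjusted p = 0.0027, adjusted p = 0.4 with an estimated correlation). In these libraries the mitochondrial share was 2.22% ± 1.33 (SD, n = 21). In batch B alone, which held JGE01 and JGE02, Mef2c did not pass (−0.07). In all, 5569 genes rose and 5545 fell of 15910 tested, and the total of 11114 was 6378 in batch B alone and 7420 in batch C alone.

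**Figure D2:**
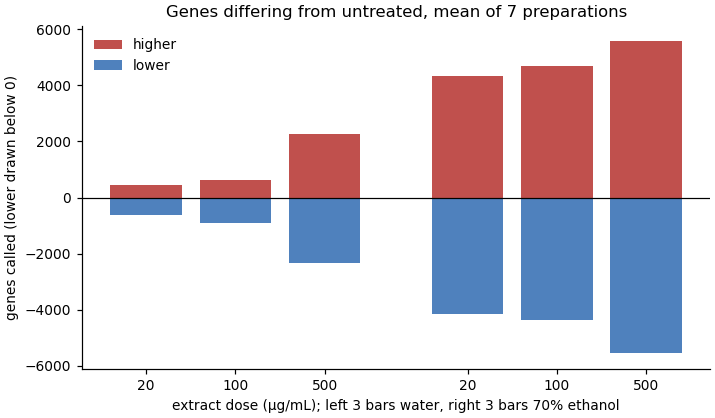
Genes higher (above 0) and lower (below 0) than untreated in the mean of 7 water or 7 ethanol preparations at each dose (µg/mL). Water extracts moved 1063, 1554 and 4609 genes at 20, 100 and 500 µg/mL, and ethanol extracts 8471, 9080 and 11114.

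The herbs given alone in water (JGW01 and JGW05, 500 µg/mL, 3 libraries each against 12 untreated) both lowered division genes and moved hypoxia genes in opposite directions. Division genes fell in 29 and 30 of 30 with the first and second herb (30 and 30 adjusted over the list alone, camera adjusted p = 7.4e-98 and 4.7e-56), and aryl hydrocarbon receptor targets rose in 6 and 7 of 7 (7 and 7 adjusted over the list alone, camera adjusted p = 8.8e-26 and 7.6e-26). Hypoxia and glycolysis genes rose in 11 of 27 with the first herb (12 adjusted over the list alone, median 0.19, camera adjusted p = 1.4e-08) and fell in 15 with the second (15 adjusted over the list alone, median −0.30, camera adjusted p = 1.9e-11). Slc2a1 rose by 0.61 ± 0.07 with the first herb, and carbonic anhydrase 9 (Car9) fell by 2.67 ± 0.19 with the second. The direct contrast, first minus second herb, gave 19 of 27 hypoxia genes higher (20 adjusted over the list alone, median 0.62, camera adjusted p = 2.1e-54), with Car9 at 3.27 ± 0.21 and the kinase gene Pdk1 at 1.02 ± 0.08. Nrf2 targets were lower with the first herb in 14 of 27 (16 adjusted over the list alone, camera adjusted p = 7.2e-21), Gsta1 by 2.98 ± 0.18 and Gsta4 by 1.48 ± 0.18. Cyp1b1 was lower by 0.70 ± 0.10 and Aldh3a1 by 1.40 ± 0.17. Matrix genes were higher with the first herb in 7 of 26 (13 adjusted over the list alone, camera adjusted p = 1.3e-15) and in 13 without the low-mitochondrial libraries, with Ccn2 at 1.83 ± 0.12. Against untreated, 1549 genes passed with the first herb (660 higher, 889 lower) and 3092 with the second (1483 higher, 1609 lower), and 495 separated the herbs (270 and 225). Without the libraries numbered 1 these were 512, 1115 and 46, and Aldh3a1, Cyp1b1 and Gsta4 no longer passed the contrast, and without those numbered 2 the first and last were 1006 and 275. JGW01 lay in batch A, while JGW05 lay in batch A for the library numbered 1 and in batch B for the others. Without the libraries numbered 1 the herbs therefore shared no batch. Without the low-mitochondrial libraries the counts were 2326 for the first herb and 845 for the contrast, and with the mitochondrial share as a covariate the contrast gave 798. No water or untreated library was low-mitochondrial, so leaving those out removed only ethanol libraries from the shared fit.

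The herbs given alone in ethanol (JGE01 and JGE05, 500 µg/mL, 3 libraries each) separated much further, with 9045 genes between them (4460 higher with the first herb, 4585 lower). The herbs lay in different batches, JGE01 in batch B (mitochondrial share 3.47 to 4.34%, fragments 239.1 to 252.9 nt) and JGE05 in batch C (0.88 to 2.08%, 201.3 to 218.9 nt). A batch or quality difference among treated libraries therefore cannot be told apart from the herb. Ndrg1 (ENSMUSG00000005125, chr15, 66929318 to 66969640) rose from 105 ± 2.58 CPM in untreated cultures to 1080 ± 58.8 CPM with the first herb and 236 ± 15.6 CPM with the second (SD, n = 3 each). Of 27 hypoxia and glycolysis genes 24 rose and 3 fell with the first herb (24 and 3 adjusted over the list alone, median 0.91, camera adjusted p = 7.9e-27), and Car9 was higher than with the second herb by 6.16 ± 0.25. The second herb raised ATF4 targets, 25 of 26 with 1 lower (25 and 1 adjusted over the list alone, median 1.76, camera adjusted p = 9.8e-14). Trib3, a pseudokinase induced by stress (chr2, 152337422 to 152344032), went from 7.23 ± 0.422 to 311 ± 58.9 CPM (SD, n = 3 each), against 8.27 ± 1.3 CPM with the first herb. Atf3 rose by 4.45 ± 0.11 and Ddit3 by 3.82 ± 0.10. Chaperones of the endoplasmic reticulum rose in 16 of 18 (16 adjusted over the list alone, camera adjusted p = 6.2e-06), with Hspa5, which encodes BiP, at 2.19 ± 0.17, and heat shock genes in 10 of 14 (10 adjusted over the list alone, camera adjusted p = 1.7e-04). The second herb lowered 13 of 14 myogenic regulators (13 adjusted over the list alone, median −1.29, camera adjusted p = 3.4e-07), Mef2c by 3.19 ± 0.14 and the fusion peptide gene Mymx by 2.83 ± 0.17. Contractile genes fell in 32 and rose in 4 of 45 (32 and 4 adjusted over the list alone, camera adjusted p = 1.1e-07), with cardiac actin (Actc1) at −1.88 ± 0.07. Mitochondrially encoded genes fell in 12 of 13 there (12 adjusted over the list alone, camera adjusted p = 0.0057, adjusted p = 0.4 with an estimated correlation). Both herbs lowered division genes, 29 and 29 of 30 (30 and 29 adjusted over the list alone, camera adjusted p = 5.3e-44 and 1.9e-13). Against untreated, 5126 genes passed with the first herb (2577 without the libraries numbered 1) and 11084 with the second.

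**Figure D3:**
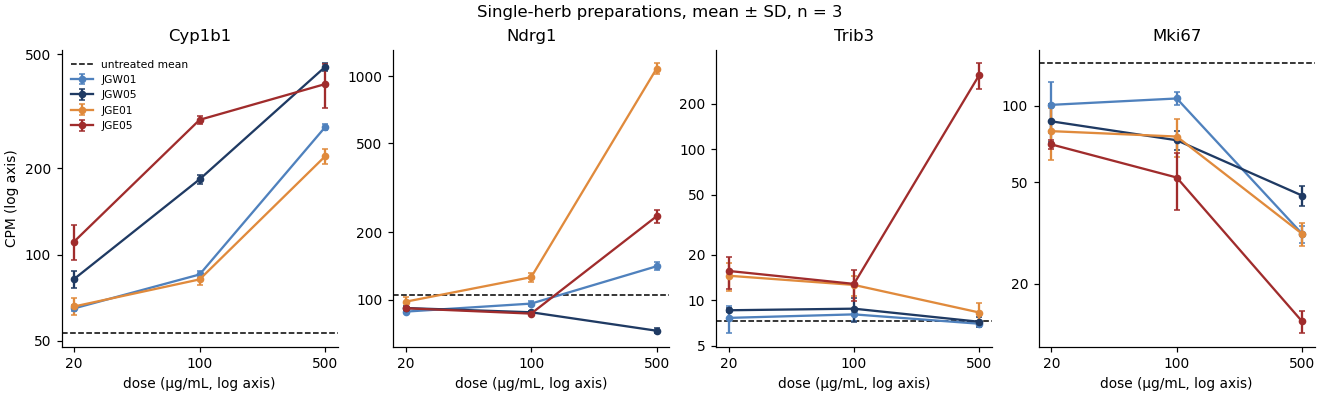
Levels (CPM, log axis) of Cyp1b1, Ndrg1, Trib3 and Mki67 against dose (µg/mL, log axis) for the single-herb preparations, points and bars giving mean ± SD of 3 libraries and the dashed line the untreated mean. Trib3 reached 311 CPM with JGE05 at 500 µg/mL against 7.23 in untreated cultures, and Ndrg1 reached 1080 CPM with JGE01.

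Order of extraction was read from the 2:1 and 1:2 preparations, as the mean of herbs extracted and then mixed minus the mean of herbs mixed and then extracted (6 against 6 libraries at 500 µg/mL). In water the mixed-then-extracted libraries were all of batch A and 5 of the 6 others of batch B, and in ethanol they were of batches B and C and the others of C and D. In water 1 gene passed, Txnip, which binds thioredoxin (chr3, 96557957 to 96561883), lower by 0.42 ± 0.06 (edgeR adjusted p = 3.9e-04), while 370 of 15910 passed an unadjusted 0.05. DESeq2 called 12 genes, and each of the 3 leave-outs by library number gave 0 (149 to 397 unadjusted). Inflammation genes had a median of −0.11 there, 0 passing over all genes and 1 lower adjusted over the list alone (camera adjusted p = 2.2e-04). In ethanol 2819 genes passed, 1424 higher and 1395 lower where extraction came first, and 6 of 30 splits of the same libraries, the real one included, gave as many (up to 4267). Contractile genes were higher in 24 of 45 (31 adjusted over the list alone, median 0.31, camera adjusted p = 1.0e-12), with Actc1 at 0.70 ± 0.06 and embryonic myosin (Myh3) at 1.06 ± 0.16. Nrf2 targets were lower in 17 of 27 (18 adjusted over the list alone, camera adjusted p = 9.8e-14), Nqo1 by 1.43 ± 0.18, and ATF4 targets lower in 14 and higher in 1 of 26 (14 and 1 adjusted over the list alone, camera adjusted p = 2.2e-09). Cyp1b1 was lower by 0.69 ± 0.07, and hypoxia genes were higher in 15 of 27 (16 adjusted over the list alone, camera adjusted p = 6.1e-10), Car9 by 1.47 ± 0.12. The ethanol total was 884 without the libraries numbered 1, 1438 without those numbered 2, 5053 without the low-mitochondrial libraries and 2023 in batch C alone, where only the 1:2 ratio had both orders (2 against 3 libraries).

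Mixtures were compared with the mean of the single herbs on the log scale (2:1 and 1:2 mixed and then extracted, minus 3:0 and 0:3, 6 against 6 libraries at 500 µg/mL). A departure from that mean does not by itself show that the herbs interacted. In water 23 genes departed, 18 higher and 5 lower. The collagenase gene Mmp13 was higher by 0.92 ± 0.16, lipoprotein lipase (Lpl) by 0.43 ± 0.07 and Pi15 by 0.84 ± 0.08, while Ache was lower by 0.73 ± 0.10 and the sarcomere gene Myot by 0.47 ± 0.09. The water total was 1 to 13 with 1 library number left out, 50 with DESeq2 and 57 without the low-mitochondrial libraries, and 560 genes passed an unadjusted 0.05. None of the low-mitochondrial libraries was a water extract. In ethanol 3581 genes departed, 2082 higher and 1499 lower, and 4 of 30 splits, the real one included, gave as many (up to 5023). ATF4 targets were lower in mixtures in 20 of 26 (21 adjusted over the list alone, median −0.48, camera adjusted p = 9.3e-22), Ddit3 by 1.46 ± 0.07 and Atf3 by 1.53 ± 0.08. Cholesterol genes were higher in 22 of 23 (22 adjusted over the list alone, median 0.53, camera adjusted p = 2.3e-20), Hmgcs1 by 0.72 ± 0.06 and Insig1 by 0.75 ± 0.07. Myogenic regulators were higher in 8 of 14 (9 adjusted over the list alone, camera adjusted p = 2.2e-06), Myod1 by 0.86 ± 0.06. The growth factor gene Areg was lower by 2.07 ± 0.15 and Ptgs2, which encodes cyclooxygenase 2, by 1.83 ± 0.07. Without the libraries numbered 1 the ethanol total was 2029.

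Ethanol minus water extracts over the 7 matched preparations at 500 µg/mL (21 against 21 libraries) gave 4299 genes higher and 4604 lower of 15910. Hypoxia and glycolysis genes were higher in ethanol in 22 of 27 and lower in 1 (22 and 1 adjusted over the list alone, median 0.74, camera adjusted p = 2.4e-19), with Ndrg1 at 2.09 ± 0.05 and Slc2a1 at 1.60 ± 0.05. ATF4 targets were higher in 18 and lower in 2 of 26 (20 and 3 adjusted over the list alone, camera adjusted p = 5.0e-07), with Gdf15 at 2.16 ± 0.10. With same-numbered controls summed and no batch term, 19 of these targets were higher and 5 lower. Against untreated their median was 1.76 in JGE05 and 0.89 in JGE04, and −0.16, −0.12 and −0.12 in JGE01, JGE02 and JGE08 beside −0.03, −0.18 and −0.20 in the matched water preparations. Myogenic regulators were lower in 12 and higher in 1 of 14 (12 and 1 adjusted over the list alone, median −0.62, camera adjusted p = 2.3e-05), with Myod1 at −0.70 ± 0.05, and Igf1 was lower by 2.82 ± 0.08. Cyp1b1 was lower in ethanol by 0.36 ± 0.06. Mitochondrially encoded genes were lower in 12 of 13 (12 adjusted over the list alone, camera adjusted p = 8.8e-04, adjusted p = 0.36 with an estimated correlation). The total of 8903 was 5800 with the mitochondrial share as a covariate. Water libraries lay in batches A and B and ethanol libraries in B, C and D. Batch B was the only one with both solvents and held no matched pair of preparations, so no batch gives this contrast alone. The batch term rests on near-repeat untreated libraries and on preparations split over batches. A batch difference among treated libraries therefore cannot be told apart from the solvent. The mitochondrial share at this dose was 4.63% in water and 2.22% in ethanol.

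**Figure D4:**
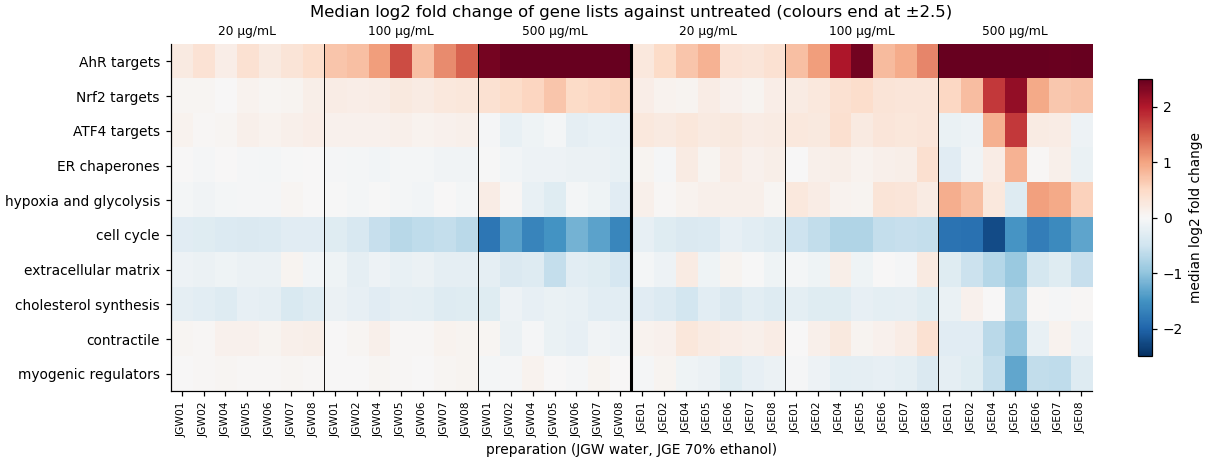
Median log2 fold change against untreated (colour, ending at ±2.5) of 10 gene lists for each preparation and dose. Aryl hydrocarbon receptor targets were above 0 and cell cycle genes below 0 in both solvents at 500 µg/mL, and ATF4 targets reached a median of 1.76 with JGE05.

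At 100 µg/mL water extracts (21 against 12 libraries) raised 5 of 7 aryl hydrocarbon receptor targets (6 adjusted over the list alone, median 1.08, camera adjusted p = 2.3e-15), Cyp1b1 by 1.18 ± 0.05. They lowered 28 of 30 division genes (30 adjusted over the list alone, median −0.55, camera adjusted p = 1.3e-55), Mki67 by 0.82 ± 0.10, and 12 of 23 cholesterol genes (16 adjusted over the list alone, camera adjusted p = 2.2e-16). Ethanol extracts at that dose raised Cyp1b1 by 1.29 ± 0.05 and 18 of 26 ATF4 targets (18 adjusted over the list alone, median 0.27, camera adjusted p = 3.4e-05), Chac1 by 0.55 ± 0.06. All 30 division genes fell (30 adjusted over the list alone, median −0.66, camera adjusted p = 4.7e-21), and mitochondrially encoded genes in 12 of 13 (13 adjusted over the list alone, camera adjusted p = 0.0021, adjusted p = 0.45 with an estimated correlation), 3 with same-numbered controls summed. Without the low-mitochondrial libraries 6 of them fell, but those libraries were chosen by a low share of these same genes. Totals were 1554 for water (629 higher, 925 lower) and 9080 for ethanol (4697 and 4383, and with same-numbered controls summed 2 of 30 splits gave as many, the real one included). The water total was 652 with same-numbered controls summed, 844 and 942 in batches A and B alone and 3244 with the mitochondrial share as a covariate. The ethanol total was 5384 with controls summed, 911 in batch B alone, 3156 in batch C alone and 5782 without the libraries numbered 3.

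At 20 µg/mL genes of cholesterol synthesis and cell division fell in both solvents, as they did in vehicle cultures against untreated ones (medians −0.13 and −0.21). Water extracts lowered 15 of 23 cholesterol genes (19 adjusted over the list alone, median −0.28, camera adjusted p = 8.8e-30), Hmgcs1 by 0.51 ± 0.04. They lowered 26 of 30 division genes (28 adjusted over the list alone, median −0.30, camera adjusted p = 6.8e-42), Ccna2 by 0.38 ± 0.03, and Txnip by 0.52 ± 0.03. Cyp1b1 rose by 0.46 ± 0.04. Ethanol extracts lowered Hmgcs1 by 0.58 ± 0.03 and 17 of 23 cholesterol genes with 2 higher (17 and 2 adjusted over the list alone, median −0.32, camera adjusted p = 9.5e-08). ATF4 targets rose in 19 and fell in 2 of 26 (20 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 7.0e-06), with Trib3 at 0.97 ± 0.08, and division genes fell in 25 of 30 (25 adjusted over the list alone, camera adjusted p = 4.0e-11). Large falls in ethanol at this dose included the long noncoding Kcnq1ot1 (−1.43 ± 0.09), Dpysl2 (−1.27 ± 0.08) and Zfhx3 (−1.13 ± 0.06), of which Dpysl2 (−0.25) and Zfhx3 (−0.31) did not pass in batch B alone. Nuclear respiratory chain genes rose in 23 of 32 (23 adjusted over the list alone, camera adjusted p = 4.0e-05, adjusted p = 0.27 with an estimated correlation), and the mitochondrial share was 2.77% ± 1.63 (SD, n = 21). Totals were 1063 for water (445 higher, 618 lower, and with same-numbered controls summed 2 of 30 splits, the real one included, gave as many as the real one) and 8471 for ethanol (4317 and 4154). The water total was 310 with same-numbered controls summed, 284 and 290 in batches A and B alone, 424 against vehicle and 2600 without the batch term. The ethanol total was 932 in batch B alone, 5405 in batch C alone and 2777 against vehicle.

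The slope over doses, fitted without controls (63 libraries per solvent), was per 5-fold step in dose. Aryl hydrocarbon receptor targets rose with dose in 7 of 7 for water and 7 of 7 for ethanol (7 and 7 adjusted over the list alone, camera adjusted p = 3.3e-14 and 4.3e-13). Cyp1b1 (ENSMUSG00000024087, chr17, 79701537 to 79715061) rose by 1.17 ± 0.04 per step in water and 0.94 ± 0.04 in ethanol. Nrf2 targets rose in 26 and 25 of 27 (26 and 25 adjusted over the list alone, camera adjusted p = 4.6e-20 and 5.0e-17), Gsta1 by 2.13 ± 0.11 and 2.54 ± 0.13. All 30 division genes fell with dose in both solvents (30 and 30 adjusted over the list alone, camera adjusted p = 1.0e-33 and 9.9e-33), Mcm5, a replication helicase subunit, by 0.67 ± 0.04 and 0.81 ± 0.05 per step. Tagln fell by 0.79 ± 0.05 and Cxcl5 rose by 2.36 ± 0.09 per step in water, and Igf1 fell by 1.37 ± 0.14 in ethanol. The slope passed for 7437 of 15599 genes in water (3768 rising) and 7726 of 16055 in ethanol (4108 rising).

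Vehicle against untreated cultures (9 against 9 libraries of batches A, B and D) showed small shifts in many genes, 4824 of 14347 (2291 higher, 2533 lower), of which 9 exceeded 2-fold. Division genes were lower in 29 (29 adjusted over the list alone, median −0.21, camera adjusted p = 4.6e-19), Mki67 by 0.36 ± 0.02, and cholesterol genes in 17 of 23 (17 adjusted over the list alone, median −0.13, camera adjusted p = 1.3e-09), Hmgcs1 by 0.23 ± 0.01. Chaperones of the endoplasmic reticulum were lower in 12 of 18 (12 adjusted over the list alone, camera adjusted p = 4.0e-05), Hsp90b1 by 0.24 ± 0.02. The total was 803, 790 and 849 in batches A, B and D alone, 1606 with same-numbered controls summed, 3101 without the libraries numbered 3 and 3095 with fragment length as a covariate. With controls summed, 23 division genes, 14 cholesterol genes and 6 chaperones of the endoplasmic reticulum were lower.

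Dexa, the label's name for dexamethasone, a glucocorticoid, was compared with vehicle within batch D, as were the other 5 compounds (3 against 3 libraries each, doses not in the labels). The compounds lay in library sets 10-1 to 10-3 and the vehicle libraries in set D1-1. Mean fragment length was 222.2 nt in the compounds and 253.7 nt in the vehicle libraries of all batches. A difference between library sets therefore cannot be told apart from the compounds. Of 20 glucocorticoid targets 19 rose and 1 fell (19 and 1 adjusted over the list alone, median 1.64, camera adjusted p = 4.3e-13). Fkbp5 (chr17, 28399094 to 28517527) went from 24.7 ± 1.19 to 326 ± 27.7 CPM (SD, n = 3 each), Tsc22d3 rose by 2.63 ± 0.09 and Per1 by 1.24 ± 0.13. Zbtb16 went from 1 count over 3 vehicle libraries to 113, a ratio of 112 (95% counting interval 19.6 to 4450). Muscle atrophy genes rose in 11 and fell in 2 of 18 (11 and 2 adjusted over the list alone, camera adjusted p = 1.6e-04), Fbxo32 by 1.21 ± 0.10 and Trim63 by 1.12 ± 0.11. Of 30 division genes 25 fell and 1 rose (25 and 1 adjusted over the list alone, camera adjusted p = 2.3e-12). Contractile genes rose in 34 and fell in 3 of 45 (34 and 3 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.11 with an estimated correlation). The acute phase gene Serpina3n rose by 9.21 ± 0.28, and its paralogue Serpina3m went from 4 counts over 3 vehicle libraries to 2907, a ratio of 718 (95% counting interval 280 to 2640), though either may include reads of the other. In all 3802 genes rose and 3568 fell of 15666, and the total of 7370 was 4718 without the libraries numbered 1. The mitochondrial share was 2.07%.

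Calcitriol, the active form of vitamin D, raised its receptor gene Vdr by 2.40 ± 0.09, from 62.7 ± 1.96 to 332 ± 10.4 CPM (SD, n = 3 each). Cyp24a1, the enzyme that degrades calcitriol (chr2, 170482708 to 170497145), went from 2 counts over 3 vehicle libraries to 5098, a ratio of 2620 (95% counting interval 725 to 21600). It lowered 29 of 30 division genes (29 adjusted over the list alone, median −1.83, camera adjusted p = 6.2e-22), Aurkb by 2.41 ± 0.10 and cyclin D1 (Ccnd1) by 4.45 ± 0.18. Cholesterol genes fell in 19 of 23 (19 adjusted over the list alone, median −1.04, camera adjusted p = 4.8e-11), and lipogenic genes in 10 of 12 with 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 5.5e-05), Fads2 by 1.66 ± 0.12. Mmp13 rose by 7.37 ± 0.28. In all 4243 genes rose and 3725 fell, and the total of 7968 was 4507 without the libraries numbered 2 and 5068 with fragment length as a covariate. The mitochondrial share was 1.7%.

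Resveratrol raised 22 of 26 Nrf2 targets (24 adjusted over the list alone, median 1.10, camera adjusted p = 2.4e-14). Gsta4 (chr9, 78182774 to 78209349) went from 7.2 ± 0.197 to 302 ± 78.8 CPM (SD, n = 3 each) and Srxn1 rose by 2.25 ± 0.07. Division genes fell in 25 and rose in 1 of 30 (25 and 1 adjusted over the list alone, median −1.63, camera adjusted p = 3.7e-14), cyclin B1 (Ccnb1) by 3.02 ± 0.10. Matrix genes fell in 21 and rose in 1 of 26 (22 and 1 adjusted over the list alone, camera adjusted p = 1.3e-07), periostin (Postn) by 2.98 ± 0.10. Cyp1b1 fell by 0.33 ± 0.12, which turned to 0.11 with fragment length as a covariate. It stood at −0.08 without the low-mitochondrial libraries, where only the Resveratrol library numbered 3 remained. In all 4291 genes rose and 4235 fell, and the total of 8526 was 5399 without the libraries numbered 2 and 3492 with fragment length as a covariate. The mitochondrial share was 1.4%.

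Celecoxib, an inhibitor of cyclooxygenase 2, raised 22 of 27 hypoxia and glycolysis genes (24 adjusted over the list alone, median 0.45, camera adjusted p = 3.1e-15), Bnip3 by 0.99 ± 0.09 and Car9 by 1.49 ± 0.28. ATF4 targets rose in 13 and fell in 1 of 26 (15 and 1 adjusted over the list alone, camera adjusted p = 2.1e-08), with Trib3 at 1.35 ± 0.18 and the serine synthesis gene Psat1 at 0.60 ± 0.07. Ptgs2, which encodes the drug's target, stood at 0.14 ± 0.12 (edgeR adjusted p = 0.45), and passed at 0.22 with the mitochondrial share as a covariate. The total was 2922 (1538 higher, 1384 lower). It was 319, 1111 and 1140 without the libraries numbered 3, 1 and 2, and 5255 without the low-mitochondrial libraries, at a mean mitochondrial share of 2.72%. No Celecoxib or vehicle library was low-mitochondrial, so that setting removed only libraries of other compounds from the shared fit.

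Palmitric acid, as the labels spell the saturated fatty acid, raised 15 of 24 fatty acid oxidation genes (18 and 1 lower adjusted over the list alone, median 0.49, camera adjusted p = 1.8e-10). Angptl4, an inhibitor of lipoprotein lipase (chr17, 33773750 to 33781830), went from 16.1 ± 0.397 to 197 ± 30.3 CPM (SD, n = 3 each), and Cpt1a, which carries fatty acids into mitochondria, rose by 1.36 ± 0.12, Plin2 by 1.21 ± 0.11 and Pdk4 by 0.55 ± 0.11 (0.57 and not past the test without the libraries numbered 2). Cholesterol genes fell in 18 and rose in 1 of 23 (19 and 1 adjusted over the list alone, median −0.67, camera adjusted p = 3.9e-14), and lipogenic genes in 8 of 12 with 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 1.9e-06), Fasn by 0.95 ± 0.08. Of 30 division genes 22 fell (24 adjusted over the list alone, camera adjusted p = 3.9e-14). The total was 3618 (1824 higher, 1794 lower), 575 and 1670 without the libraries numbered 2 and 3, at a mean mitochondrial share of 2.32%.

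Arachidonic acid, a polyunsaturated fatty acid, lowered 15 of 23 cholesterol genes with 2 higher (15 and 2 adjusted over the list alone, median −0.50, camera adjusted p = 5.6e-07). The desaturase gene Scd1 fell by 1.12 ± 0.13, with 9 of 12 lipogenic genes lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.062 with an estimated correlation). Without the low-mitochondrial libraries only the Arachidonic acid library numbered 1 remained, and the lipogenic median was −0.35. The chemokine genes Ccl8 and Ccl7 rose by 2.52 ± 0.22 and 1.98 ± 0.26. Mitochondrially encoded genes fell in 8 of 13 (11 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.52 with an estimated correlation). Their median was −1.13 without the low-mitochondrial libraries, which were chosen by a low share of these same genes. At a mean mitochondrial share of 1.18%, 3566 genes rose and 2891 fell. The total of 6457 was 1024 and 2249 with fragment length or mitochondrial share as a covariate, and 2368 and 1795 without the libraries numbered 2 and 3.

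Between the fatty acids 625 genes passed, 423 higher and 202 lower with Arachidonic acid. Angptl4 was lower with Arachidonic acid by 3.40 ± 0.17, Cpt1a by 1.20 ± 0.12 and Pdk4 by 0.96 ± 0.11, with 10 of 24 fatty acid oxidation genes lower and 1 higher (12 and 3 adjusted over the list alone, camera adjusted p = 1.7e-08). Division genes were higher in 24 of 30 (27 adjusted over the list alone, median 0.73, camera adjusted p = 5.9e-32), Mcm5 by 0.87 ± 0.09, and the chemokine gene Ccl11 was higher by 2.18 ± 0.20. The total was 261, 178 and 95 without the libraries numbered 1, 2 and 3. Of these libraries 2 of Arachidonic acid and 1 of Palmitric acid held a mitochondrial share under 1%. Splitting them by that share in place of the fatty acid gave 2768 genes. Without the low-mitochondrial libraries only the Arachidonic acid library numbered 1 remained, and the division gene median was 0.74. Doses may differ between the compounds, since the labels give none.

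**Figure D5:**
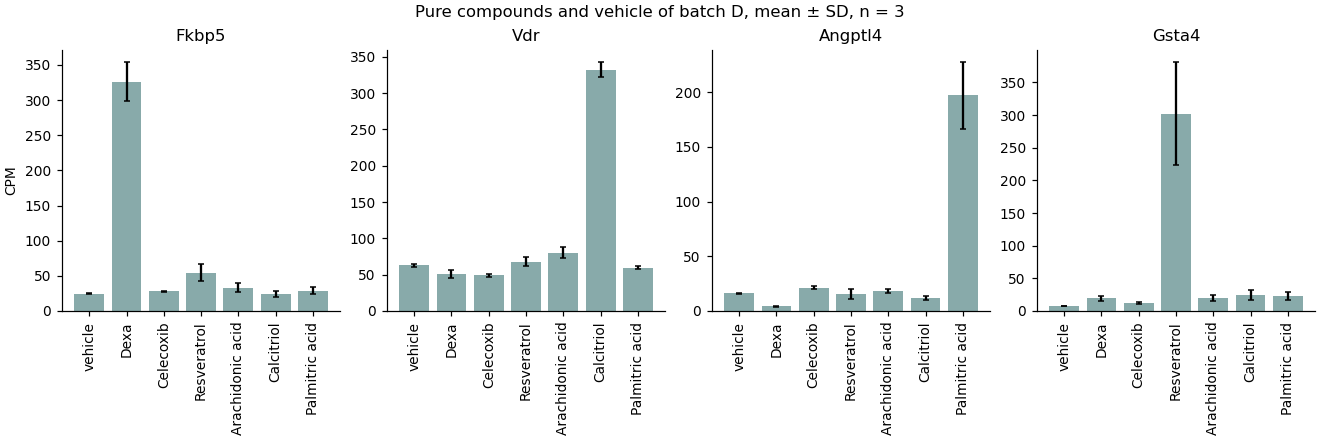
Levels (CPM, linear axis from 0) of Fkbp5, Vdr, Angptl4 and Gsta4 in vehicle and the 6 compounds of batch D, bars and error bars giving mean ± SD of 3 libraries. Fkbp5 was highest with Dexa (326 CPM), Vdr with Calcitriol (332 CPM), Angptl4 with Palmitric acid (197 CPM) and Gsta4 with Resveratrol (302 CPM).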

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

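The contrasts of effects between solvents, and the tests on fragment length, untreated batches, control numbers and the mitochondrial covariate, were chosen after results were seen. A test of the difference between water and ethanol picked out 3 results at 500 µg/mL. The gap between the single herbs differed between the solvents in 6632 genes (3398 higher and 3234 lower in ethanol minus water), 2229 without the libraries numbered 1, and 3 of 30 splits reached the count, the real one included. ATF4 targets were lower in 22 of 26 there (24 adjusted over the list alone, median −1.68, camera adjusted p = 5.0e-18), Trib3 at −5.26 ± 0.36 and Ptgs2 at −4.35 ± 0.19, and myogenic regulators were higher in 12 of 14 (12 adjusted over the list alone, camera adjusted p = 1.2e-06). JGE01 lay in batch B, JGE05 in batch C, JGW01 in batch A and JGW05 in batches A and B. A batch or quality difference among treated libraries therefore cannot be told apart from this contrast. The effect of extraction order differed in 726 genes (9 and 339 without the libraries numbered 1 and 2, 459 without the low-count filter, 1712 without the low-mitochondrial libraries), with contractile genes higher in 13 of 45 (22 adjusted over the list alone, median 0.37, camera adjusted p = 1.4e-13, 21 higher without the low-mitochondrial libraries) and Car9 at 1.91 ± 0.23. The departure of mixtures from single herbs differed in 1757 genes (396 and 1035 without the libraries numbered 1 and 2), with ATF4 targets lower in 17 of 26 (18 adjusted over the list alone, camera adjusted p = 8.4e-18), Ddit3 at −1.47 ± 0.11, and cholesterol genes higher in 16 of 23 (21 adjusted over the list alone, camera adjusted p = 4.3e-16).

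A mitochondrial share under 1% marked 20 libraries, all ethanol extracts or compounds. The mean of untreated libraries was only 0.51 points lower in batches C and D than in batch A (4.38 and 4.01 against 4.71%). That argues against a shift shared by all libraries of a batch. Same-numbered untreated libraries were near-repeats, so they cannot show whether treated cultures or their libraries differed between batches. Ethanol extracts averaged 4.07% in batch B, 1.97% in batch C and 1.80% in batch D, so such a difference stays open. Library or RNA quality may contribute: within groups the share followed fragment length at Pearson r = 0.70 and Spearman rho = 0.67 (81 libraries, permutation p = 1e-05 for each, the smallest possible), and at r = 0.68 without the 2 libraries farthest in fragment length. A treatment effect stays open, since 35.6% of the variance lay between the 21 ethanol groups against a median of 30.6% with labels shuffled within batches (permutation p = 0.27).

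Vehicle and untreated cultures differed in 4824 genes, nearly all by under 2-fold. Control RNA sequenced again in each batch could raise that number. Over splits with 2 vehicle and 1 untreated library of each batch on a side, the 9 that took the same numbers in each batch gave a median of 12 genes (highest 1083), and 60 that mixed numbers gave 0 or 1. The count with same-numbered controls summed, 1606, also rests on fewer libraries and no batch term, so it does not size this share. Batches A, B and D alone gave 803, 790 and 849 genes. An effect of 0.02% DMSO on division and cholesterol genes stays open as the biological explanation.

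Ethanol extracts at 20 µg/mL moved 8471 genes against 1063 for water. With the mitochondrial share as a covariate the counts were 7436 for ethanol and 2063 for water. That share as a linear term thus did not account for the gap. It is a single proxy and raised the water count too, so library or RNA quality stays open as a cause. A shift between ethanol cultures and the untreated ones unrelated to dose may be part of it. Of the genes called at 20 µg/mL in ethanol, 54.8% moved the same way from 100 to 500 µg/mL, just under the bound of 55 set before, against 75.4% in water. Batch B alone gave 932 genes and batch C alone 5405, with different preparations. The mean mitochondrial share of ethanol extracts over all doses was 4.07% in batch B and 1.97% in batch C. An effect of ethanol-soluble compounds at this dose was not excluded.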

How the results depend on the processing

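The settings with fragment length, mitochondrial share, low-mitochondrial libraries and summed controls, and each setting for the contrasts between solvents, were chosen after results were seen. Of 412 counts of genes under alternatives, 307 stayed within 1.5 times the reported count. DESeq2 size factors and the replicate number as a block moved none of the 30 counts by more, and untreated in place of vehicle none of 7. Values that moved by more follow by comparison, with the number of genes past the test, and the cause was not tested except where batches or left-out libraries make fewer samples. With the DESeq2 test the counts were 12 for order in water and 50 for departure in water. With all libraries in 1 fit the counts were 7 for order in water, 44 for departure in water, 1282 for order between solvents, 4771 for Celecoxib, 5479 for Palmitric acid and 971 for the fatty acids. Without the low-count filter the count was 459 for order between solvents. Without the batch term they were 2928 for water at 100, 2600 for water at 20, 5 for order in water, 38 for departure in water and 1703 for order between solvents. Against vehicle in place of untreated libraries they were 1032 for water at 100, 424 for water at 20 and 2777 for ethanol at 20. Batch A alone gave 844 for water at 100, 284 for water at 20 and 803 for vehicle. The count for order in water moved there as well but is not given, since it rested on 1 library extracted and then mixed. Batch B alone gave 6378 for ethanol at 500, 942 for water at 100, 911 for ethanol at 100, 290 for water at 20, 932 for ethanol at 20 and 790 for vehicle. Batch C alone gave 3156 for ethanol at 100 and 5405 for ethanol at 20. Batch D alone gave 849 for vehicle. With same-numbered controls summed and no batch term the counts were 2822 for water at 500, 652 for water at 100, 5384 for ethanol at 100, 310 for water at 20, 3 for order in water, 1239 for order between solvents and 1606 for vehicle. With fragment length as a covariate they were 2499 for water at 100, 1494 for order between solvents, 3095 for vehicle, 3492 for Resveratrol, 1024 for Arachidonic acid and 5068 for Calcitriol. With the mitochondrial share as a covariate they were 3244 for water at 100, 2063 for water at 20, 798 for herbs in water, 5 for order in water, 48 for departure in water, 5800 for solvent, 1342 for order between solvents, 4815 for Celecoxib and 2249 for Arachidonic acid. Without the low-mitochondrial libraries they were 3038 for water at 100, 1637 for water at 20, 2326 for JGW01, 845 for herbs in water, 5 for order in water, 5053 for order in ethanol, 57 for departure in water, 1712 for order between solvents, 5255 for Celecoxib, 5638 for Resveratrol, 1674 for Arachidonic acid and 327 for the fatty acids. For the water extracts, JGW01, Celecoxib, and herbs, order and departure in water, this setting removed no library of the compared groups. It removed only other libraries of the shared fit. For Resveratrol, Arachidonic acid and the fatty acids this setting left 1 library in a group. Its spread was then taken from other groups, so these counts cannot test those comparisons. List tests passing at 0.05 fell from 381 to 196 with the correlation estimated per list. Cyp1b1 with Resveratrol turned from −0.33 to 0.11 with fragment length as a covariate.

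Leaving out all libraries of 1 number in turn gave these lowest and highest counts, doses in µg/mL. Counts were 2481 to 4079 for water at 500, 597 to 1479 for water at 100, 5782 to 8213 for ethanol at 100, 314 to 653 for water at 20, 512 to 1273 for JGW01, 1115 to 2661 for JGW05 and 2577 to 4669 for JGE01. They were 46 to 387 for herbs in water, 0 to 0 for order in water, 884 to 3186 for order in ethanol, 1 to 13 for departure in water, 2029 to 3376 for departure in ethanol, 2229 to 5934 for herbs between solvents and 9 to 503 for order between solvents. The remaining ranges were 396 to 1585 for departure between solvents, 3101 to 4770 for vehicle, 4718 to 6001 for Dexa, 319 to 1140 for Celecoxib, 5399 to 7911 for Resveratrol, 1795 to 6468 for Arachidonic acid, 4507 to 7498 for Calcitriol, 575 to 2435 for Palmitric acid and 95 to 261 for the fatty acids.

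The replicate number as a block gave 4533 genes for water at 500 µg/mL, 5172 for vehicle and 1 for order in water. Numbers matched untreated libraries across batches (median r 0.58, 17 of 18 pairs over 0.1) and vehicle libraries (median r 0.49, 9 of 9), but not vehicle with untreated (3 of 9) or extracts with untreated, so the reported tests are unpaired. In the self-test on simulated counts 40.3% of 1.5-fold changes were recovered for 1 preparation, 30.3% for 1 compound and 77.3% for 7 preparations. Within a batch the order contrast could be run for a single ratio only, in water at 2:1 with 1 library extracted and then mixed, so the 33 genes of batch A there say little about the contrast over both ratios, and each alternative fixed beforehand gave a value.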

Other observations

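The tests on other splits of the libraries were planned, and those with summed controls were chosen after results were seen. Further gene groups moved with the ethanol extracts at 500 µg/mL. Targets of p53 rose in 14 and fell in 3 of 20 (14 and 3 adjusted over the list alone, median 0.38, camera adjusted p = 1.4e-04), with Trp53inp1 up by 0.79 ± 0.04. With same-numbered controls summed, 14 rose and 1 fell. Genes of lysosomes and autophagy rose in 16 and fell in 3 of 24 (16 and 3 adjusted over the list alone, camera adjusted p = 9.9e-04), the autophagy receptor Sqstm1 by 1.14 ± 0.05. Inflammation genes were lower with the first than the second herb in 11 and higher in 4 of 19 (11 and 4 adjusted over the list alone, median −1.10, camera adjusted p = 0.017), Ptgs2 by 3.92 ± 0.14. Adipocyte markers rose in 3 of 4 under water extracts at 500 µg/mL (3 adjusted over the list alone, camera adjusted p = 4.5e-04), with lipoprotein lipase (Lpl) at 1.48 ± 0.06, and in 3 of 5 with Calcitriol (3 adjusted over the list alone, camera adjusted p = 0.002), Lpl at 1.81 ± 0.07.

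Chance was weighed by other splits of the same libraries, each real split counted among 30 unless said. Shares were not adjusted over the comparisons, and 1 of 30 is the smallest that 30 splits can give. The splits mixed unlike treatments or doses, which can widen the spread and lower their counts. Apart from the slopes, they did not keep libraries within their batches where a fit spanned batches. Since same-numbered controls are near-repeats, comparisons with untreated or vehicle libraries that rest on them were split again with those controls summed. For water extracts 1 of 30 splits reached the real count at each dose, with 0, 180 and 1 genes in the highest other split at 500, 100 and 20 µg/mL against 4609, 1554 and 1063. With controls summed it was 1, 1 and 2 of 30, with 1035, 87 and 2554 against 2822, 652 and 310. For ethanol extracts it was also 1 of 30 at each dose, with 4173, 3884 and 2604 against 11114, 9080 and 8471, and with controls summed 1, 2 and 1 of 30, with 2786, 6110 and 20 against 8848, 5384 and 5963. Taken singly, water at 500 and 100 and ethanol at 500 and 20 µg/mL thus each had a share under 0.05, with single and with summed controls. The splits could lower their own counts and crossed batches, so these shares do not by themselves exclude chance. It is not excluded either for water at 20 and ethanol at 100 µg/mL, where the share with summed controls was above 0.05. The split of water at 20 with 2554 genes, several times the real count, points to other structure among those libraries. Solvent (8903, highest other 2) and the slopes in water (7437, highest other 1) and ethanol (7726, highest other 4817) each had 1 of 30. Each of them taken singly thus had a share under 0.05, with the same limit from splits that mix unlike treatments or doses. For solvent this share also does not separate a difference between batches, since no matched pair of preparations shared a batch. Departure in water (23, highest other 6) also had 1 of 30. Its count was 1 to 13 with 1 library number left out, so chance stays open there.

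It is not excluded for order in water (3 of 30, real 1, highest other 1), order in ethanol (6 of 30, real 2819, highest other 4267), departure in ethanol (4 of 30, real 3581, highest other 5023) and the solvent contrasts of herbs (3 of 30, real 6632, highest other 6830), order (2 of 30, real 726, highest other 809) and departure (3 of 30, real 1757, highest other 3324). The single herbs had 1 of 30 splits each, with 151, 1225, 1185 and 7268 against 1549, 3092, 5126 and 11084 for JGW01, JGW05, JGE01 and JGE05, and vehicle had 1 of 100 (4824, highest other 2305). Summing same-numbered controls left 10 splits for these 5, too few for a share under 0.05, with 1126, 2183, 4511 and 10425 genes (highest other 0, 0, 0 and 1) for the herbs and 1606 (highest other 1) for vehicle. With 10 splits, the herb contrasts gave 495 (highest other 0) in water and 9045 (highest other 4) in ethanol. Dexa, Celecoxib, Resveratrol, Arachidonic acid, Calcitriol and Palmitric acid gave 7370, 2922, 8526, 6457, 7968 and 3618 (highest other 0 for each), also among 10 splits. The fatty acids against each other gave 625 (2 of 10, highest other 2768). That other split, several times the real count, divided the 6 libraries by mitochondrial share rather than by fatty acid. It set Arachidonic acid 1 and Palmitric acid 1 and 3 (2.24, 2.82 and 3.34%) against the low-mitochondrial libraries (0.85, 0.81 and 0.45%).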
